A study of Mus musculus with 6 samples.

How the data were processed

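The series measured RNA of sorted small-intestinal ILC3s by Smart-seq2, per the labels' protocols, in 6 mouse libraries. Each came from 2000 sorted cells and 2 ng of purified RNA. The groups were taken from the sample titles and genotype labels: 3 control samples (floxed Batf without Cre) and 3 Batf-deficient samples (floxed Batf with PLZF-Cre), which the series design calls biological replicates. The labels give no batch, litter, sex or date.

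The values are raw counts per gene symbol as deposited by the authors in a single table, whole numbers whose totals differ between libraries. The genome build was mm10 per the submitters' processing notes. The aligner, the counting tool, the gene annotation and whether counting used strand are not given in the sources used here. Smart-seq2 carries no molecular identifiers, so counts are reads rather than molecules, and counting intervals and floors cover counting error only. Reads of near-identical genes, of pseudogenes, of overlapping genes and of antisense partners can be assigned to the wrong gene. Of 25075 symbols, 24623 (98.2%) were found in a table of mouse gene names, and no row was blank or a summary. Coordinates are from GENCODE M21, which is on the same build.

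Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with its minimum count of 10, which left 15261. Libraries were scaled by TMM, with factors of 1.17, 1.14 and 1.11 for the control and 0.859, 0.857 and 0.914 for the Batf-deficient libraries. A quasi-likelihood model (glmQLFit with robust=TRUE, glmQLFTest, two-sided) was fitted to all 6 libraries with group as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are labelled Batf-deficient over labelled control. CPM values use TMM-scaled library sizes, except shares of counts, which use library totals. For genes with 1 to 5 counts in a group, ratios of counts per scaled total are given with 95% counting intervals; for genes with none, the bound uses 3 counts over the group. A self-test simulated 15261 genes at the mean shares of the control libraries and the library sizes of this comparison. Only a small part of the genes was changed, as many up as down. The simulation held no wide difference in composition such as that between these groups, so its rates do not measure the calls made here. The test called 20.9% of 67 genes changed 1.5-fold, 52.2% of 67 changed 2-fold and 77.3% of 66 changed 4-fold, and 7.41% of its calls were false. The shifted list was found, and none of the others was called. Genes were drawn independently of each other, so this does not measure how often lists are called where genes move together.

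Gene lists were fixed before the data were examined: 23 of ILC biology, signalling and metabolism and 13 of other cell types. Each was tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes and adjustment over the 36 lists. Camera compares a list with the other genes tested, so its higher and lower are relative to these. The genes named in the text were Batf, then the 12 with the largest positive and the 12 with the largest negative log2 fold change among those past the threshold, with a mean log2 CPM of at least 3 and no overlap between groups, leaving out gene models with placeholder names. To these were added 11 genes named in advance (Il22, Il17a, Il17f, Tbx21, Ifng, Il23r, Ahr, H2-Ab1, Cd74, Ccr6, Ncr1). From each list, members past the threshold with the lowest p were eligible; the rule allowed 6, and at most 3 are given here beyond genes already named. Some genes that the rule names are not reported here. Members of the added panel and of the list of 18 abundant acinar genes, and the genes singled out in the closing section, were chosen after their values were seen. The 6 heat shock and 20 immediate early members were split from a list fixed in advance. The 11 further acinar genes were chosen after the acinar pattern was seen but before their own values were. Of the 10 further heat shock genes, Hspd1 and Hspe1 had been seen when the list was made, and the others had not.

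Libraries of a group were compared by a chi-square of their counts over genes with at least 20 counts. Batf-deficient replicates 1 and 2 were the most alike, with a mean chi-square of 2.36 per gene, where 1 is sampling noise alone; other pairs of that group had 16.5 and 19.8 and pairs of control libraries 14.8 to 24.2. They were counted as separate samples because the series design calls them biological replicates. The chi-square does not show this, since repeated preparations from the same RNA may also differ by more than sampling noise, so whether they come from separate animals is uncertain, and their average was tried as an alternative. The replicate numbers shared by the groups were not used as pairs. Lists were set against the panel by two-sided permutation of genes between list and panel, in which genes are not independent replicates. Genes that a list shares with the panel, such as Il7r and Txk, were left out of the list for the permutation. They were kept in the difference of medians that is printed beside its p-value.

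Alternatives planned before the data were examined were DESeq2 (version 1.42.0) size factors, library totals, no filter and a stricter filter on low counts (at least 10 counts in every library of a group and 5 CPM in 3 libraries), the DESeq2 Wald test, limma voom without and with sample weights, a fit without robust dispersion, a replicate block, other thresholds, camera with ranks or an estimated correlation, fry, and leaving out each library in turn. Alternatives added after seeing the data were scaling on a panel of 19 genes shared by ILCs and T cells and averaging Batf-deficient replicates 1 and 2. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No columns of the table were left unused.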

Results

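Bulk RNA sequencing was carried out on group 3 innate lymphoid cells (ILC3s), tissue-resident lymphocytes that make IL-22 and IL-17, sorted from the small intestine of mice on a B6 background. Each sample held 2000 cells that were lineage-negative, CD90-positive and KLRG1-negative, and libraries were made by Smart-seq2, a full-length cDNA method for small inputs, from 2 ng of RNA. The labels gave 2 groups of 3 biological replicates: control mice with a floxed Batf gene and no Cre, and mice in which the PLZF-Cre transgene was added to delete Batf, which encodes a basic leucine zipper transcription factor of the AP-1 family. The deposited table held raw counts for 25075 gene symbols. Total counts were 9080012, 15399111 and 17334207 in control replicates 1 to 3, and 8420533, 8228513 and 13615895 in Batf-deficient replicates 1 to 3. At these depths 3 counts corresponded to between 0.173 and 0.365 CPM (counts scaled to a common library total). Genes with at least 10 counts numbered 14931, 16124 and 16408 in the control libraries and 13095, 13035 and 14190 in the libraries labelled Batf-deficient.

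The targeted gene was examined first, as a check of the labels. Batf lies on chromosome 12 from 85686669 to 85709087 (plus strand, mm10), and its transcript Batf-201 has 3 exons. Its level was 15.2, 15.3 and 18.95 CPM in the control libraries and 38.3, 41.3 and 41.3 CPM in the libraries labelled Batf-deficient. The means were 16.5 ± 2.13 and 40.3 ± 1.77 CPM (SD, n = 3 each), so that Batf was 2.44-fold higher in the libraries labelled Batf-deficient (log2 fold change 1.29, SE 0.16, edgeR adjusted p = 1.70e-05). The target gene therefore went against the label, and the groups are called labelled control and labelled Batf-deficient below. Scaling on a panel of 19 genes shared by innate lymphoid and T cells reversed the direction to -1.06 (edgeR adjusted p = 6.01e-05). The panel was chosen after the data were seen. The alternatives fixed in advance gave 0.91 to 1.41. Over all alternatives, panel scaling included, the adjusted p by edgeR, DESeq2 or limma voom ran from 1.40e-10 to 0.000387. Counts per gene do not show which exons the reads came from, and the floxed exons are not given in the sources used here, so the total count of Batf checks the deletion only in part.

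The labelled groups were compared over all genes, to address which transcripts of intestinal ILC3s differ with Batf. With TMM factors, the libraries labelled Batf-deficient had more RNA of genes of ILCs and T cells (Il22, Il17a, Tbx21, Cd3g) and of inducible heat shock proteins. These examples stayed higher with panel scaling, whereas Ahr, Il17f, Ccr6 and the medians of most ILC and T cell lists turned negative. The median was -1.64 for CCR6+ lymphoid tissue inducer-like genes, -0.85 for cytotoxic granule genes and -0.62 for ILC1 and NCR+ ILC3 genes. It was -0.28 for ILC3 transcription factors and receptors and -0.25 for αβ T cell markers. Those of ILC3 cytokines (0.52) and γδ T cell markers (0.70) stayed positive. The labelled control libraries had more RNA of pancreatic digestive enzymes, intestinal epithelium, plasma cells, B cells, stroma and endothelium. Of 15261 genes tested, 9821 (64.4%) passed the edgeR quasi-likelihood test at an adjusted p of 0.05, 4612 of them higher and 5209 lower in the libraries labelled Batf-deficient. Among these, 2957 were at least 2-fold higher and 4111 at least 2-fold lower, while 401 and 2056 passed 8-fold. The CPM of the 3 libraries of one group did not overlap those of the other for 10860 genes (71.2%), where chance gives 10%. The first principal component, which held 87.5% of the variance of log2 CPM, separated the groups.

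The split between higher and lower genes depended on the scaling. With library totals in place of TMM factors, 3048 genes were higher and 6488 lower, and the median of all genes shifted by -0.38. With the panel of ILC and T cell genes, 328 were higher and 13125 lower, and the median shifted by -2.35. All 5209 genes that were lower with TMM factors were also lower with the panel, whereas 3007 of the 4612 higher genes became lower calls and 328 were higher under both. Fold changes below use TMM factors, and the panel-scaled value is given beside each group of genes whose direction it turned.

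**Figure D1:**
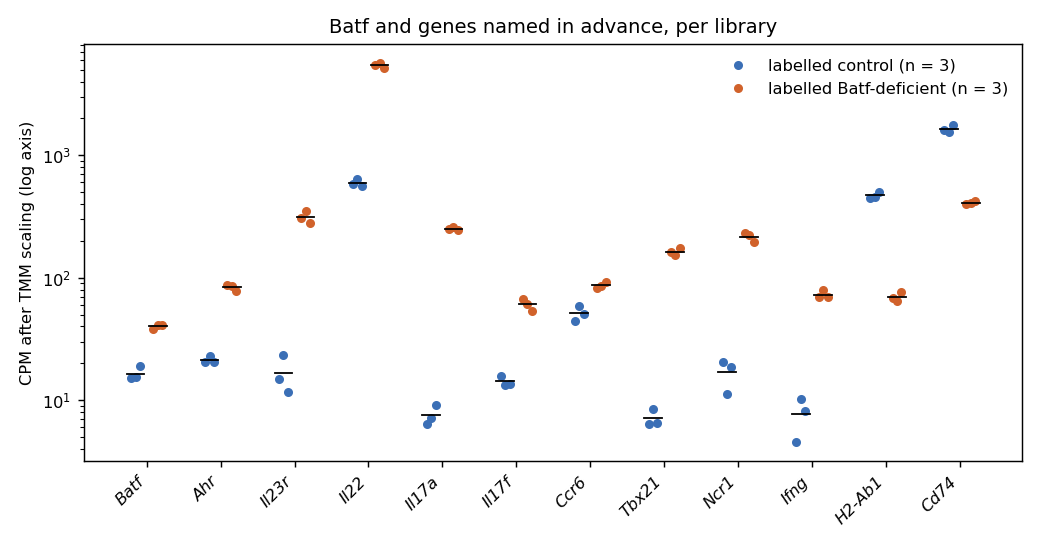
CPM after TMM scaling (log axis) of Batf and 11 genes named in advance, with a point for each library and a line at the mean of each labelled group (n = 3). H2-Ab1 and Cd74 were lower and the other genes higher in the libraries labelled Batf-deficient; scaling on the ILC and T cell panel turned Batf, Ahr, Il17f and Ccr6 to negative values, of which that of Il17f did not pass the edgeR test.

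The naming rule took genes with a mean log2 CPM of at least 3, no overlap between groups and no placeholder name. Of the 12 such genes with the largest increase in the libraries labelled Batf-deficient, 6 were heat shock genes. Hspa1a, an inducible Hsp70 chaperone (chromosome 17, 34969190 to 34972156), went from 73.3 ± 9.48 to 24736 ± 329.95 CPM (log2 fold change 8.40, SE 0.13, edgeR adjusted p = 5.93e-13). Its near-identical neighbour Hspa1b (34956436 to 34959238) had a log2 fold change of 6.84, and how reads were shared between these genes is uncertain. The co-chaperones Hsph1, Dnajb1 and Dnaja4 and the cytosolic chaperone Hsp90aa1 followed at 5.43, 5.26, 4.84 and 5.19. Xist, the long noncoding RNA of X inactivation, was at 0.902 ± 0.465 CPM in the labelled control and 230 ± 50.2 CPM in the labelled Batf-deficient libraries. The remaining genes of the 12 with the largest increase were Pcp4, a calmodulin regulator (5.22), Mid1, a ubiquitin ligase (5.04), the cytokine Il17a (5.04), the transcriptional co-activator Cited4 (4.81) and H2-Q5, a class Ib histocompatibility gene of a multigene family (4.80). All 12 passed the edgeR test, with adjusted p between 5.93e-13 and 2.62e-08, and stayed higher with panel scaling, with values from 2.45 for H2-Q5 to 6.05 for Hspa1a.

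The 11 genes given here with the largest decrease all encode secreted enzymes of the exocrine pancreas. Amy2a4, a pancreatic amylase (chromosome 3, 113279843 to 113291449), had 24564 ± 480.5 CPM in the labelled control libraries and took 2.85%, 2.85% and 2.69% of their counts, more than any other gene. In the libraries labelled Batf-deficient it had 5 counts in all, a ratio of 131124 (95% counting interval 56188 to 403837). The elastase Cela2a fell from 13459 ± 274.0 CPM to 3 counts, a ratio of 119847 (41009 to 581153). Ctrb1 (chymotrypsinogen), Pnlip (pancreatic lipase), Cela3b (elastase) and Cpb1 (carboxypeptidase) had 2 counts each there, with ratios of 111549 (30880 to 921101), 100882 (27927 to 833018), 35661 (9872 to 294463) and 32434 (8978 to 267821). Cel (carboxyl ester lipase) and Cpa1 (carboxypeptidase) had 1 count each, with ratios of 126898 (22776 to 5012240) and 103407 (18559 to 4084370). Try4 (trypsin), Amy2a1 (amylase) and Pnliprp1 (a lipase-related protein) had no count in any library labelled Batf-deficient. Against a floor of 3 counts over that group, they were at least 45471-, 24677- and 10508-fold lower. Each of the 11 passed the edgeR test, with adjusted p between 1.94e-13 and 8.96e-11. Trypsins, amylases and elastases are multigene families whose members can share reads, so the values of single members are uncertain.

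Summed over 18 abundant acinar genes, a list drawn up after the data were seen, these transcripts made up 11.99% ± 0.225 of the counts of the labelled control libraries and 0.000905% ± 0.000101 of the libraries labelled Batf-deficient (SD, n = 3 each). The median log2 fold change of the 18 genes was -16.12, and -14.69 with the genes at 0 set to their bound. Over the same libraries the 19 panel genes of ILCs and T cells went from 0.115% ± 0.00418 to 0.476% ± 0.00552 of counts. The median panel gene was 5.44-fold higher in the libraries labelled Batf-deficient (log2 fold change 2.44, range 0.69 for Sh2d1a to 3.63 for Cd247), and 18 of the 19 passed the edgeR test. Bcl11b, Cd247, Il7r, Lck, Thy1 and Txk of the panel also belong to lists fixed in advance.

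**Figure D2:**
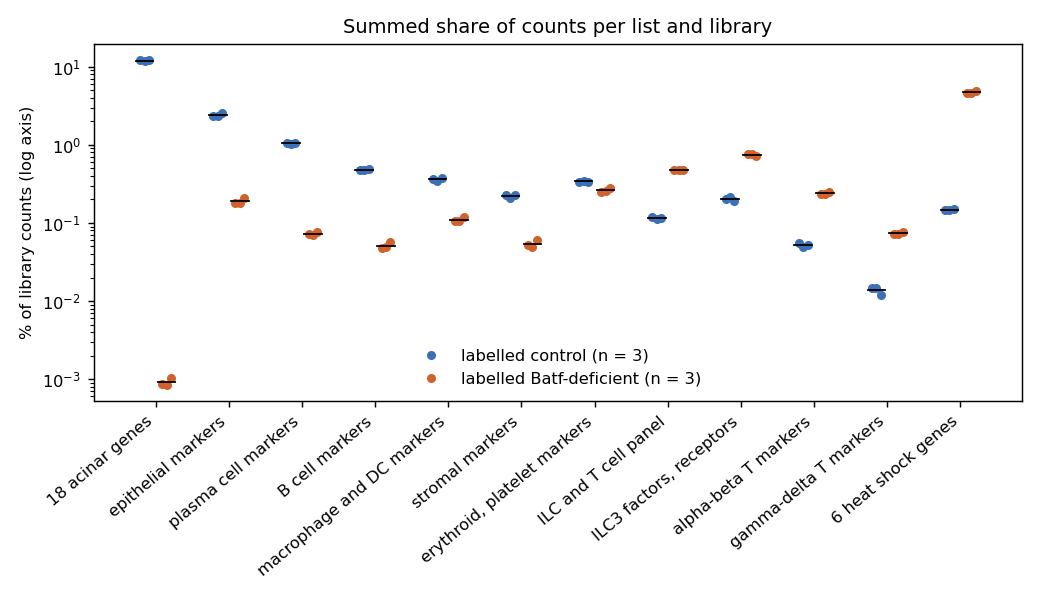
Summed share of library counts (percent, log axis) for 12 groups of genes, with a point for each library and a line at the mean of each labelled group (n = 3). The 18 acinar genes take 11.99% of counts in the labelled control and 0.000905% in the labelled Batf-deficient libraries, and the 6 heat shock genes 0.147% and 4.69%. Groups share some genes, such as Lyz1 among the epithelial and the macrophage markers.

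Marker genes of cell types other than ILCs were measured in lists fixed before the data were examined. Of 26 intestinal epithelial markers, 23 were lower and 2 higher in the libraries labelled Batf-deficient (median -4.62), and their summed share was 2.40% ± 0.124 against 0.191% ± 0.0161. The simple-epithelium keratin Krt8 fell from 3933 ± 190.3 to 143 ± 8.95 CPM and the apolipoprotein Apoa1 from 1315 ± 146 to 1.37 ± 0.0859 CPM. The higher members, named after their values were seen, were the antimicrobial lectins Reg3b and Reg3g, at 0.72 and 0.28, and at -1.63 and -2.07 with panel scaling. The camera adjusted p was 8.27e-11 for the epithelial list, and the adjusted p = 0.0823 with an estimated correlation. Of 12 plasma cell markers 9 were lower and 3 higher (median -3.46), with Igha, the constant region of IgA, at 6828 ± 319.0 against 468 ± 16.3 CPM, and Jchain, which joins IgA dimers, at 1606 ± 164.9 against 75.9 ± 8.74 CPM. Of 16 B cell markers 13 were lower and 1 higher (median -3.96), with the receptor component Cd79a at 34.8 ± 2.86 against 1.54 ± 0.262 CPM. The plasma and B cell lists had camera adjusted p = 0.0122 and 0.000496 (adjusted p = 0.0832 and 0.0902 with an estimated correlation).

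Of 20 macrophage and dendritic cell markers 16 were lower and 3 higher (median -3.13), with the lipid carrier Apoe and the lysozyme Lyz1, which Paneth cells also make, at log2 fold changes of -4.03 and -3.47. Of 19 stromal markers 17 were lower and 1, Thy1 (CD90, which the sort selected for), was higher (median -4.20), with the collagens Col1a1 and Col3a1 at -6.67 and -6.04. Of 14 endothelial markers 13 were lower and 1 higher (median -3.05), with the VEGF receptor Kdr at -3.89 and the fenestral protein Plvap at -3.42. Of 10 enteric neuron and glia markers 8 were lower and none higher (median -3.15). These 4 lists had camera adjusted p = 0.000693, 8.15e-06, 0.000195 and 0.0105 in that order (adjusted p = 0.0687, 0.0663, 0.0630 and 0.0832 with an estimated correlation). Of 7 granulocyte and mast cell markers 3 were lower, and the list did not pass (median -0.96, camera adjusted p = 0.337). In that list Mcpt1, a mucosal mast cell protease, had no count in the libraries labelled Batf-deficient and was at least 40.6-fold lower. The 7 erythroid and platelet markers did not pass as a list (median -0.20, camera adjusted p = 0.729), with 2 higher and 3 lower over all genes tested and 4 lower adjusted over the list alone. Its members went both ways: the platelet chemokine Pf4 fell from 8.94 CPM to 3 counts, a ratio of 76.3 (25.9 to 371), while the globins Hbb-bs and Hbb-bt were at 0.41 and 0.68 with TMM factors and at -1.94 and -1.68 with panel scaling.

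**Figure D3:**
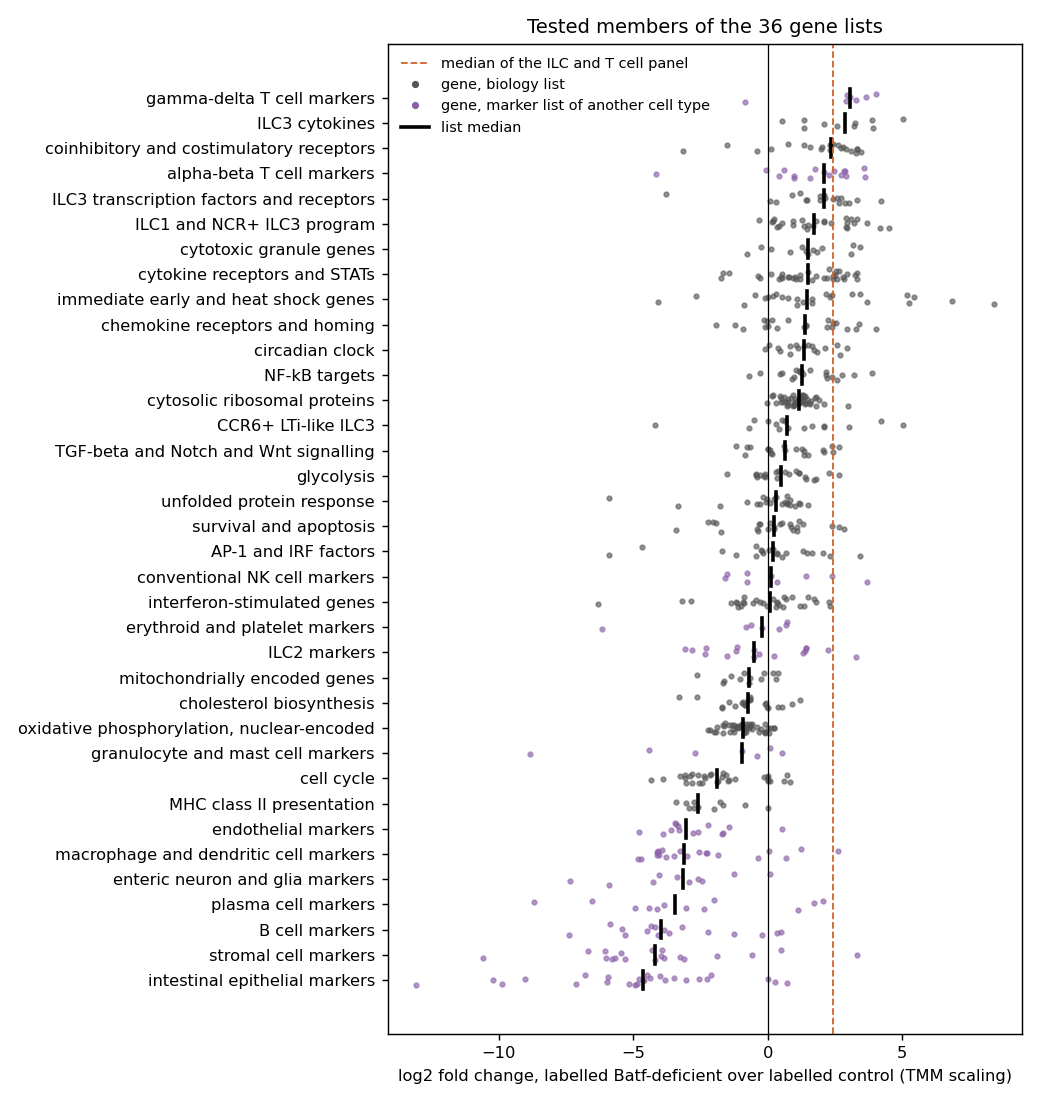
Log2 fold change (labelled Batf-deficient over labelled control, TMM scaling) of each tested member of the 36 lists, with black bars at list medians and a dashed line at the panel median of 2.44. Epithelial, stromal and B cell markers lie lowest, at medians of -4.62, -4.20 and -3.96, and panel scaling places the median of all genes lower by 2.35, which turns 19 list medians from positive to negative, 14 of them of lists that passed camera with TMM factors.

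By camera with a preset correlation, 28 of the 36 lists passed, 16 higher and 12 lower in the libraries labelled Batf-deficient; with an estimated correlation 2 passed, the ILC1 and NCR+ ILC3 program and the cytokine receptors and STATs. With panel scaling 21 passed: the calls of the B cell, plasma cell, macrophage and dendritic cell, stromal, enteric neuron and glia, ribosomal protein, glycolysis and TGF-β, Notch and Wnt lists ended, and the unfolded protein response passed as lower. Counts of members adjusted over the list alone were equal to those over all genes for 27 lists, and are given beside the list for the other 9. The labelled control libraries differed from the others in their share of acinar, epithelial and other tissue transcripts beside each of the lists below.

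Core ILC3 transcripts were more abundant with TMM factors in the libraries labelled Batf-deficient. Batf itself was higher there with TMM factors and lower with panel scaling. Of 19 ILC3 transcription factors and receptors, 16 were higher and 1 was lower (median 2.08, and -0.28 with panel scaling). Kit, Id2 and Nfil3 had log2 fold changes of 3.01, 2.88 and 2.58 and stayed positive with panel scaling at 0.66, 0.52 and 0.23. Ahr, the aryl hydrocarbon receptor, had 1.96 and, with panel scaling, -0.40, while the IL-23 receptor gene Il23r had 4.22 and 1.85. The camera adjusted p of this list was 4.68e-08 (adjusted p = 0.0515 with an estimated correlation).

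Of 10 ILC3 cytokine genes 9 were higher and none lower (median 2.87, and 0.52 with panel scaling). Il22 (chromosome 10, 118204942 to 118210047) went from 594 ± 45.8 to 5422 ± 279.8 CPM, a log2 fold change of 3.19 (SE 0.09, edgeR adjusted p = 6.73e-11) and of 0.83 with panel scaling. Il17a (chromosome 1, 20730905 to 20734496) went from 7.55 ± 1.38 to 251 ± 6.84 CPM, with 5.04 and a panel-scaled 2.69, and Tnf had 3.88 and 1.53. Il17f, by contrast, had 2.09 and a panel-scaled -0.26. The list had a camera adjusted p of 6.42e-06 (adjusted p = 0.0515 with an estimated correlation). T cell markers were higher in the same libraries with TMM factors. Medians were 3.04 for γδ T cell markers (0.70 with panel scaling) and 2.09 for αβ T cell markers (-0.25 with panel scaling). Of 16 genes of CCR6+ lymphoid tissue inducer-like ILC3s, 11 were higher and 3 lower, or 12 and 3 adjusted over the list alone (median 0.71, and -1.64 with panel scaling). Ccr6 was at 51.2 ± 7.37 and 87.2 ± 5.17 CPM (log2 fold change 0.77, SE 0.13, edgeR adjusted p = 0.000250), which panel scaling reversed to -1.59. The amino acid transporter Slc7a8 fell by 4.18 on the log2 scale. The camera adjusted p was 0.00410 (adjusted p = 0.0823 with an estimated correlation).

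Genes of ILC1s and NCR-positive ILC3s were higher beside them. Of 28 members 22 were higher, or 23 adjusted over the list alone, and none lower (median 1.73, and -0.62 with panel scaling). With panel scaling 10 were higher and 15 lower. Tbx21, which encodes T-bet (chromosome 11, 97098071 to 97115331), went from 7.16 ± 1.19 to 163 ± 9.92 CPM (log2 fold change 4.50, SE 0.15, edgeR adjusted p = 1.49e-10). Ncr1, the NKp46 receptor gene, and Ifng had log2 fold changes of 3.69 and 3.22, and these 3 genes stayed higher with panel scaling, at 2.15, 1.35 and 0.87. Il2rb, a receptor chain for IL-2 and IL-15, had 3.32 and the lectin-like receptor Klrb1b 2.92. The list passed camera with an adjusted p of 1.91e-08 and, with an estimated correlation, of 0.0478. Of 13 cytotoxic granule genes 10 were higher and 2 lower (median 1.49, and -0.85 with panel scaling), among them the proteoglycan Srgn (3.42) and the granzyme inhibitor Serpinb9 (3.16), while Serpinb6b had 1.83 and a panel-scaled -0.52. Their camera adjusted p was 0.000571 (adjusted p = 0.0673 with an estimated correlation).

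Receptor genes moved in the same direction with TMM factors. Of 35 cytokine receptors and STATs 26 were higher, or 27 adjusted over the list alone, and 4 lower (median 1.48, and -0.87 with panel scaling), among them Il2rb, Cish (2.84), a feedback inhibitor of STAT5, and Il2rg (2.44), the common γ chain, which had 0.08 and lost its call with panel scaling. This list had a camera adjusted p of 1.91e-08 and, with an estimated correlation, of 0.0478. Of 22 coinhibitory and costimulatory receptors 18 were higher and 2 lower (median 2.34, and -0.000578 with panel scaling), with Icos at 3.29 and Cd96 at 3.46, while the tetraspanin Cd81 was at -3.14. Of 22 chemokine receptors and homing genes 13 were higher and 3 lower (median 1.38, and -0.98 with panel scaling), with Cxcr6 at 3.29, the retention marker Cd69 at 4.03 and the gut-homing integrin Itgb7 at 3.38. Their camera adjusted p were 7.71e-07 and 0.000909 (adjusted p = 0.0832 with an estimated correlation for each). Of 21 genes of TGF-β, Notch and Wnt signalling 11 were higher, or 12 adjusted over the list alone, and 4 lower (median 0.63, and -1.73 with panel scaling). Notch1, its nuclear partner Rbpj and Runx1 had log2 fold changes of 2.43, 2.38 and 2.09, and panel-scaled values of 0.07, 0.02 and -0.26. The camera adjusted p was 0.0107 (adjusted p = 0.186 with an estimated correlation).

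Antigen presentation by MHC class II was lower in the libraries labelled Batf-deficient under each scaling. Of 11 genes 10 were lower and none higher (median -2.61, and -4.96 with panel scaling), and their summed share went from 0.355% ± 0.0170 to 0.0662% ± 0.00450 of counts. H2-Ab1, the class II β chain, was at 472 ± 29.4 and 69.7 ± 5.71 CPM (log2 fold change -2.76, SE 0.11, edgeR adjusted p = 5.69e-10). The invariant chain Cd74 was at 1647 ± 106.3 and 411 ± 14.2 CPM, or 4.01-fold lower. H2-Eb1 and H2-Aa had -2.76 and -2.61. The list passed camera with an adjusted p of 8.33e-05 (adjusted p = 0.0832 with an estimated correlation). B cell and macrophage markers, whose cells carry class II, were lower in the same libraries, at medians of -3.96 and -3.13.

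Of 21 AP-1 and IRF factors, the families from which Batf takes its partners, 10 were higher and 4 lower, and the list did not pass (median 0.20, mean -0.03, camera adjusted p = 0.119). Its median was -0.18 with library totals and -2.15 with panel scaling. Jun rose (log2 fold change 3.43, SE 0.10, edgeR adjusted p = 7.63e-11), Fosl1 fell by 5.89, and Junb had 2.31 and a panel-scaled -0.05. Interferon-stimulated genes did not pass either: 11 of 32 were higher, or 13 adjusted over the list alone, and 11 lower (median 0.08, mean -0.18, camera adjusted p = 0.479). Their median was -0.30 with library totals and -2.27 with panel scaling. The GTPases Gbp6 and Igtp had 2.33 and 2.27, and -0.03 and -0.09 with panel scaling, and the immunoproteasome subunit Psmb8 had 1.36 and -0.99.

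Stress and activation genes were higher as a group with TMM factors. Of 26 immediate early and heat shock genes 19 were higher and 3 lower (median 1.48, and -0.87 with panel scaling). The heat shock members Hspa1a, Hspa1b, Dnajb1, Hsp90aa1, Hsph1 and Hspa8 were all higher under each scaling, and their summed share went from 0.147% ± 0.00333 to 4.69% ± 0.178 of counts. Hspa8 had a log2 fold change of 3.70. The other 20, immediate early genes, went from 0.776% ± 0.0241 to 2.26% ± 0.0985 of counts, with 13 higher and 3 lower (median 0.91, and -1.44 with panel scaling). The whole list had a camera adjusted p of 1.17e-07 (adjusted p = 0.0832 with an estimated correlation). All 20 NF-κB targets passed the edgeR test, 18 of them higher and 2 lower (median 1.29, and -1.06 with panel scaling), with Nfkbid at 3.20 and Traf1 at 2.17, or 0.85 and -0.18 with panel scaling. Among these targets 2 were higher and 12 lower with panel scaling. Their camera adjusted p was 7.17e-08 (adjusted p = 0.0515 with an estimated correlation). Of 17 circadian clock genes 12 were higher and none lower (median 1.36, and -0.98 with panel scaling), with Per1 at 2.94 and Bhlhe40 at 2.67 (camera adjusted p = 5.39e-05, and adjusted p = 0.0515 with an estimated correlation). Of 23 genes of the unfolded protein response 12 were higher and 5 lower, or 12 and 6 adjusted over the list alone, and the list did not pass (median 0.32, mean -0.10, camera adjusted p = 0.0795). Its median was -0.06 with library totals and -2.04 with panel scaling, under which 23 of 23 members were lower and the list passed as lower. The chaperones Hspa5 and Pdia3 had 1.20 and 1.03, and -1.15 and -1.32 with panel scaling, while Asns, an asparagine synthetase, was at -3.34.

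Genes of division and mitochondrial respiration were lower under each scaling. Of 33 cell cycle genes 24 were lower and 3 higher (median -1.88, camera adjusted p = 8.33e-05, and adjusted p = 0.0515 with an estimated correlation), with the mitotic genes Plk1 and Ccnb2 at -4.34 and -3.89. Of 50 nuclear genes of oxidative phosphorylation 40 were lower and none higher (median -0.91, camera adjusted p = 6.53e-09, and adjusted p = 0.258 with an estimated correlation), with Sdhd, Atp5o and Sdhb at -2.13, -2.01 and -1.87. Of 13 mitochondrially encoded genes 8 were lower and none higher (median -0.68, camera adjusted p = 0.0105, and adjusted p = 0.448 with an estimated correlation). These took 6.84% ± 0.502 of counts in the labelled control and 3.49% ± 0.643 in the labelled Batf-deficient libraries. Of 23 cholesterol synthesis genes 15 were lower and 4 higher (median -0.74, camera adjusted p = 0.0145, and adjusted p = 0.0832 with an estimated correlation). Among them Pmvk, the phosphomevalonate kinase gene, had a log2 fold change of -2.62.

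Ribosomal protein genes and glycolysis went the other way with TMM factors. Of 50 cytosolic ribosomal protein genes 47 were higher and none lower (median 1.16, and -1.18 with panel scaling). With panel scaling 0 were higher and 48 lower. Rps7, Rpl19 and Rps4x had 1.91, 1.80 and 1.76, and -0.45, -0.56 and -0.59 with panel scaling; these genes have many processed pseudogenes that can take up their reads. Of 22 glycolysis genes 12 were higher and 4 lower (median 0.50, and -1.85 with panel scaling), with Hk1 at 2.26 and Aldoa at 1.41, or -0.08 and -0.94 with panel scaling. Their camera adjusted p were 8.78e-14 and 0.0145 (adjusted p = 0.195 and 0.171 with an estimated correlation). The 25 survival and apoptosis genes did not pass as a list, with 12 higher and 7 lower (median 0.25, camera adjusted p = 0.224). Its median was -0.14 with library totals and -2.11 with panel scaling. The antiapoptotic genes Bcl2a1b and Bcl2a1d, near-identical copies with uncertain read assignment, had 2.65 and 2.83.

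T cell genes were among those higher in the libraries labelled Batf-deficient. Of 17 αβ T cell markers 13 were higher, or 15 adjusted over the list alone, and 1 lower (median 2.09, and -0.25 with panel scaling). The CD3 chains Cd3g and Cd3e had log2 fold changes of 3.59 and 2.92 and panel-scaled values of 1.24 and 0.57. Of 7 γδ T cell markers 6 were higher and 1 lower (median 3.04, and 0.70 with panel scaling), with Trdc, the constant region of the δ chain, at 22.1 ± 3.18 and 212 ± 0.697 CPM. The constant genes Trgc1 and Trgc4 of the γ chain, which are similar in sequence, had 2.92 and 2.96. The camera adjusted p of these lists were 5.33e-06 and 0.000552 (adjusted p = 0.0688 and 0.0832 with an estimated correlation). Of 9 NK cell markers 3 were higher and 2 lower, or 3 and 1 adjusted over the list alone, and the list did not pass (median 0.12, and -0.27 with library totals and -2.24 with panel scaling, camera adjusted p = 0.485). Its members Prf1, the perforin gene, and Zeb2 had 1.42 and 2.38, and -0.93 and 0.03 with panel scaling. Of 17 ILC2 markers 5 were higher and 6 lower (median -0.49, camera adjusted p = 0.591), with Areg, the amphiregulin gene, at 503 ± 41.6 and 175 ± 2.62 CPM and Dgat2 and Hs3st1 at -2.81 and -2.32.

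Sample labels, differences in tissue transcripts and the difference in Xist coincided in all 6 libraries, so no comparison within a set of libraries of like composition was possible. The p-values measure the spread between these libraries. The edgeR model was fitted to all 6 libraries, and the common coefficient of variation over both groups was 24.1%. Taken by group, this coefficient was 30.9% in the labelled control and 14.0% in the labelled Batf-deficient libraries. The value of 14.0% includes the replicates that were most alike, and whether these come from separate animals is uncertain. It may therefore understate the variation between animals.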

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

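The panel scaling and the averaging of labelled Batf-deficient replicates 1 and 2 were chosen after the data were seen; the others were fixed before the data were examined. Over the 19 alternatives that give a count of genes changed, it stayed within 1.5 times its value of 9821; the other 3 tested lists alone. Of 1872 values of the named genes other than Batf under alternatives other than panel scaling, 1871 kept their direction and side of the threshold; the exception was Hbb-bs with library totals, which lost its call. Batf kept a positive log2 fold change of 0.91 to 1.41 under the alternatives fixed in advance and had -1.06 with panel scaling. Over all alternatives, panel scaling included, its adjusted p by edgeR, DESeq2 or limma voom ran from 1.40e-10 to 0.000387. Leaving out each library in turn gave 8752 to 10135 genes changed (3603 to 4705 higher, 5149 to 5451 lower), 28 lists (16 higher, 12 lower) each time and 1.19 to 1.41 for Batf. With a further 2-fold threshold 2957 genes were higher; with library totals, which shift the median of all genes by -0.38, 3048 were higher. Averaging replicates 1 and 2 gave 8867 genes. The replicate numbers did not pair the libraries: correlations of same-numbered libraries were 0.00449, 0.0209 and 0.0304, and not every library correlated best with its own number. With the replicate block 9694 genes changed (4603 higher, 5091 lower), 28 lists passed and Batf had 1.29. With an estimated correlation, which widens the error of a list by construction where its genes move together, camera called 2 lists, 2 higher and 0 lower, whereas fry, which does not compare a list with other genes, called 35.

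Camera calls are relative to the other genes. Some lists were therefore called higher with panel scaling although their medians were negative, such as CCR6+ LTi-like ILC3 (-1.64) and NF-κB targets (-1.06). The panel-scaled medians of ILC3 cytokines (0.52) and γδ T cell markers (0.70) were positive. Panel scaling gave 328 genes higher and 13125 lower, and 21 lists passed (13 higher, 8 lower, relative to the other genes). It ended the calls of 8 lists (adjusted p 0.0614 to 0.738): B cell, plasma cell, macrophage and dendritic cell, stromal, and enteric neuron and glia markers, ribosomal proteins, glycolysis, and TGF-β, Notch and Wnt; the unfolded protein response gained a call as lower. The shift with panel scaling was smaller for genes with no count in the labelled Batf-deficient libraries, such as Try4 (-18.91 to -20.22). For most other genes panel scaling by its construction subtracts about 2.35 from the log2 fold change, which turned smaller positive values negative. Besides Batf it reversed 13 named genes to lower calls: Ahr (-0.40), Ccr6 (-1.59), Serpinb6b (-0.52), Psmb8 (-0.99), Aldoa (-0.94), Rpl19 (-0.56), Rps7 (-0.45), Rps4x (-0.59), Hspa5 (-1.15), Pdia3 (-1.32), Prf1 (-0.93), Hbb-bt (-1.68) and Hbb-bs (-1.94). Another 7 had values below 0 and lost their call (adjusted p of 0.103 or more): Il17f (-0.26), Junb (-0.048), Runx1 (-0.26), Gbp6 (-0.027), Igtp (-0.088), Hk1 (-0.084) and Traf1 (-0.18). Il2rg, Notch1, Rbpj, Zeb2 and P4ha1 stayed above 0 and lost their call. The medians of 19 lists turned negative, 5 of them of lists that did not pass with TMM factors. The 14 others were those of ILC3 transcription factors and receptors (-0.28), CCR6+ LTi-like ILC3 (-1.64), ILC1 and NCR+ ILC3 (-0.62), cytotoxic granule genes (-0.85), chemokine receptors (-0.98), cytokine receptors (-0.87), coinhibitory receptors (-0.000578), TGF-β, Notch and Wnt (-1.73), circadian clock (-0.98), immediate early and heat shock genes (-0.87), glycolysis (-1.85), ribosomal proteins (-1.18), NF-κB targets (-1.06) and αβ T cells (-0.25). Depth limits the 11 acinar genes named as the largest decreases, whose values in the labelled Batf-deficient libraries rest on 0 to 5 counts each.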

Other observations

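Tests of library size, of the fixed mix of cell types, of dilution, of the immediate early genes and of the Batf transcript were chosen only after the result was seen, and that of other heat shock genes after 2 of its 10 genes, Hspd1 and Hspe1, had been seen; those of further acinar genes and other splits of the libraries were written before. Genes singled out in the next paragraph were chosen after their values were seen.

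In the libraries labelled Batf-deficient, Batf itself was higher with TMM factors and lower with panel scaling. There the single genes B2m, H2-K1 and H2-Q7 had log2 fold changes of 3.99, 2.87 and 4.29, and 1.64, 0.52 and 1.93 with panel scaling. The scavenger receptor genes Scart1 and Scart2, which γδ T cells that make IL-17 express and which the fixed list held under older symbols, had 3.65 and 6.84, and 1.30 and 4.52 with panel scaling, beside the higher Il17a, Il23r and Trdc. Of 10 heat shock genes outside the fixed lists, 7 were higher and 3 lower by the edgeR test (median 1.61), and 1 was higher and 7 were lower with panel scaling (median -0.74). Xist was at 1.32, 0.401 and 0.987 CPM in labelled control replicates 1 to 3 and at 254, 264 and 173 CPM in labelled Batf-deficient replicates 1 to 3, while the Y-linked Ddx3y was at 85.0, 114 and 69.1 CPM and 110.2, 115 and 80.8 CPM. The Y-linked Eif2s3y, Uty and Kdm5d were also present in every library, at no less than 16.4, 7.06 and 5.27 CPM. Xist RNA thus coincided with the labels, whereas Y-linked RNA was present in every library. Each labelled Batf-deficient library held Xist and Y-linked RNA together, and each labelled control library held Y-linked RNA with little Xist. Whether a library held RNA of animals of both sexes was not tested. The labels give no sex, so any effect of the sex of the animals cannot be told apart from the labelled genotype.

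Tissue transcripts were high and ILC transcripts low in the labelled control libraries, with 24564 CPM of Amy2a4 and 13459 CPM of Cela2a, although a lineage-negative, CD90-positive gate would remove acinar cells. RNA of pancreatic acinar cells is a candidate source: of 11 further acinar genes tested, none in a fixed list but including Bhlha15, which plasma cells also express, 11 were lower in the labelled Batf-deficient libraries. The tables argue against library size as the whole cause: with the log2 library total as a covariate, 1097 genes moved by more than 0.5, while the epithelial median was -4.58 (95% bootstrap interval over markers -5.44 to -3.71), against -4.62 without it. A fixed mix that includes erythroid cells is argued against by the genes of a single list: the medians of 7 marker lists spanned 4.42 log2 units, with a gap of 2.92 between the intervals of the outermost lists, because the erythroid and platelet median was -0.20. That list joins cell types that moved apart: its 5 erythroid genes lay between -0.82 and 0.68, where such a mix needs them to fall like the others, while the platelet gene Pf4 did fall (-6.17). Without that list the other 6 medians spanned 1.58, which does not decide, so a fixed mix of those cell types stays open. Dilution of ILC RNA by other RNA is a candidate for the ILC3 transcription factors and receptors, whose median lay -0.36 from the panel median (permutation p = 0.288). For the ILC1 and NCR+ ILC3 program (-0.71, permutation p = 0.206) no value decides. For the CCR6+ LTi-like genes (-1.73, permutation p = 0.000400), dilution by RNA that lacks these genes is argued against as the whole cause. RNA of other cells that carry the list's genes would raise their control level, so dilution by such RNA stays open. Sorting or tissue handling that differed between groups and an effect of the Batf genotype coincide with the labels and stay open, untested.

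Heat shock transcripts were high in the labelled Batf-deficient libraries, with Hspa1a at 24736 CPM. If the panel bounds dilution of ILC RNA in the labelled control libraries, dilution is argued against as the whole cause. The median of the 6 heat shock genes lay 1.71 log2 units above the highest panel gene, and 6 of 6 lay above it. The panel sets no firm bound, however, as ILC genes outside it lay higher, such as Il23r (4.22), Tbx21 (4.50) and Il17a (5.04). Hspa8 (3.70) lay below these. Dilution therefore stays open for heat shock genes near or below such values. How far the response extends stays open. Of 10 other heat shock genes 2 lay above the panel median, as few as a response of the first-seen genes alone would give. RNA of other cells could raise the control level of genes not confined to ILCs, by an amount that was not measured. A lower value therefore does not decide. For the same reason a general dissociation response stays open, although the immediate early genes lay at -1.53 from the panel median (permutation p = 0.00123), which would otherwise have counted against it. Warmth or time during cell isolation and the Batf genotype may each account for the pattern, coincide with the labels and were not tested.

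The Batf transcript was not lower in the labelled Batf-deficient libraries. Dilution of ILC RNA in the labelled control libraries is a candidate explanation, as Batf lay -1.16 from the panel median, with 3 panel genes below it. Batf RNA of other cells in the labelled control libraries would raise the control level, which goes against the log2 fold change of 1.29 but with the panel-scaled -1.06, and no value decides on it. Exchanged labels of the groups cannot be told apart from correct ones: Batf lay -1.40 panel SDs from the panel median, within the spread of panel genes. Transcription of the floxed gene with an exon removed would leave counts in place and stays open, as counts per gene do not resolve exons.

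Of the 10 splits of the 6 libraries into groups of 3, 1, the real split, gave as many genes (9821, and 0 for the highest of the others). For the lists, 1 gave as many (28, and 24 for the highest of the others). With 10 splits the share cannot fall under 0.05, so the splits are too few to decide.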
